A study of Danio rerio with 6 samples.

How the data were processed

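Poly(A) RNA was sequenced from regenerating caudal fins of adult AB wild-type zebrafish, collected 24 h after amputation as the regenerate with 1 adjoining ray segment, per the labels' protocols. The fish had been injected with Galloflavin at 0.12 mg per g body weight in DMSO, or with DMSO alone, and kept at 33 °C. Each library was made with a stranded kit from a pool of 10 fins. Groups and batches were taken from the labels, which give 3 DMSO and 3 Galloflavin libraries and place 1 library of each group in each of the batches B1, B2 and B3.

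Reads had been aligned with STAR 2.7.10a to the GRCz11 assembly, per the submitters' processing notes. The counting program, gene annotation and normalization method are not given in the sources used here. The deposited signal was a normalised count per gene for 19822 genes in the 6 libraries, 1 column per library and not pooled. In every column each value was a whole multiple of the smallest value above 0. Dividing by that value returned whole reads for 100% of values within 0.01 of a read. The recovered libraries held 25332141 (DMSO B1), 26094710 (Galloflavin B1), 29596335 (DMSO B2), 27903337 (Galloflavin B2), 17712157 (DMSO B3) and 18064422 (Galloflavin B3) reads. Column totals of the deposited values ran from 938945 to 1093130, so that libraries had not been scaled to equal totals. Counts scaled by library size with TMM factors, computed from the recovered reads, were 0.997 to 1.005 times the deposited values in each library. At this depth 1 read corresponded to a normalised count of 0.0338 to 0.0543, and a gene at 0 may have had up to 3 reads, a normalised count of 0.102 to 0.163. This floor covers counting error only. The counting was not stated to use strand, so overlapping and antisense genes, near-identical paralogs and the 140 identifiers that share a symbol with another identifier are uncertain.

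Of the identifiers in the table, 18682 were found in a table of zebrafish gene names. The deposited table left 2175 identifiers without a symbol, and 1444 of these were given one from that table. This naming was decided after the data were examined. No genome of the assembly used for alignment was used here, so no coordinates are given.

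The normalised counts were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, using moderated variances with a mean trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. Genes with a mean of at least 1 over the 6 libraries were kept, which left 15806. Fold changes are Galloflavin over DMSO on the log2(value + 1) scale, which understates changes of low genes. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 tested genes. There were 49 lists for metabolism, chromatin, regeneration and signalling pathways, cell cycle and growth, stress, immunity, cell types and the circadian clock, and 46 were large enough. An estimated correlation and the fry test were run beside it. Exact permutation tests of list scores used all 20 assignments of the libraries, two-sided, with 0.1 as the smallest p possible. The test, the lists, the rule for naming genes and the alternatives, apart from those named below as added, were fixed before the data were examined.

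The rule for naming genes took the 10 genes with the largest change in each direction among those that passed, with a mean of at least 5, the same sign in 3 batch pairs and a name other than a clone or identifier name. Where too few passed, it was completed with genes that passed with batch as a block and then with the lowest unadjusted p. It added lactate dehydrogenase and lactate transporter genes, regeneration genes and cyp1a, and up to 4 genes of each list that passed. No gene passed in either fit, so all 20 genes of the first part came from the last step, which passed over 1 clone-named gene among the higher and 2 among the lower. Genes named outside the rule are said to be so.

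The labels give the batch of each library, so batch number paired the libraries. Deviations from the group means correlated between libraries of the same batch at 0.10 (B1), 0.08 (B2) and 0.49 (B3), and at up to 0.38 between libraries of different batches. The first principal component of the 500 most variable genes set both B3 libraries apart from the other 4. Between any pair of libraries the chi-square per degree of freedom was 11.1 to 58.0 over genes with at least 20 reads, so no library repeated another.

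Alternatives were batch as a block, pseudocounts of 0.5 and 5, no filter and a minimum mean of 5, median-of-ratios and upper-quartile scaling, quantile normalization, robust moderation, library weights, other thresholds, each library and each batch left out, and edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered reads. Upper-quartile scaling, other thresholds for the lists, the symbols of the deposited table alone, left-out libraries for each list, the set tests with an estimated correlation or fry under a batch block, and DESeq2 on other splits of the libraries were added after the data were examined. The limma, edgeR and DESeq2 steps were tested on counts simulated for the 15806 genes from the means, library sizes and dispersions of these libraries, with 200 genes changed. For the Galloflavin comparison, limma recovered 0% of genes changed 1.5-fold, 44.0% of those changed 2-fold and 92.0% of those changed 4-fold, with 0, 7 and 13 false calls. DESeq2 recovered 18.0%, 69.5% and 97.0%, with 36, 46 and 60 false calls, and edgeR recovered 0%, 45.5% and 93.0%, with 0, 9 and 13. A simulated list of 40 genes lowered by 0.2 on the log2 scale was called by camera with the preset correlation (adjusted p = 1.22e-06) and missed with an estimated correlation (adjusted p = 0.221), and 0 of 46 unchanged lists were called. Genes were drawn independently in these counts, while in the real libraries the estimated correlation reached 0.78 for the mitosis list. The simulation therefore does not test the preset correlation for genes that vary together. Figures were drawn with matplotlib 3.10.9.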

Results

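Gene expression was compared between regenerating caudal fins of zebrafish given Galloflavin, an inhibitor of lactate dehydrogenase, and fins of fish given its solvent DMSO. Lactate dehydrogenase interconverts pyruvate and lactate. The fins were collected 24 h after amputation, when a wound epidermis covers the stump and the blastema is forming. Each group had 3 libraries, each from a pool of 10 fins, and the batches B1, B2 and B3 held 1 library of each group. The libraries contained 17712157 to 29596335 reads in the genes of the table, with the lowest depth in both B3 libraries.

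The first principal component held 45.6% of the variance and placed both B3 libraries at 14.3 and 15.06, against -16.5 to -1.24 for the other 4. On the second component, with 24.7%, each Galloflavin library lay below the DMSO library of its batch, at -0.356 against 8.24 in B1, -11.5 against 12.7 in B2 and -7.37 against -1.74 in B3.

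**Figure D1:**
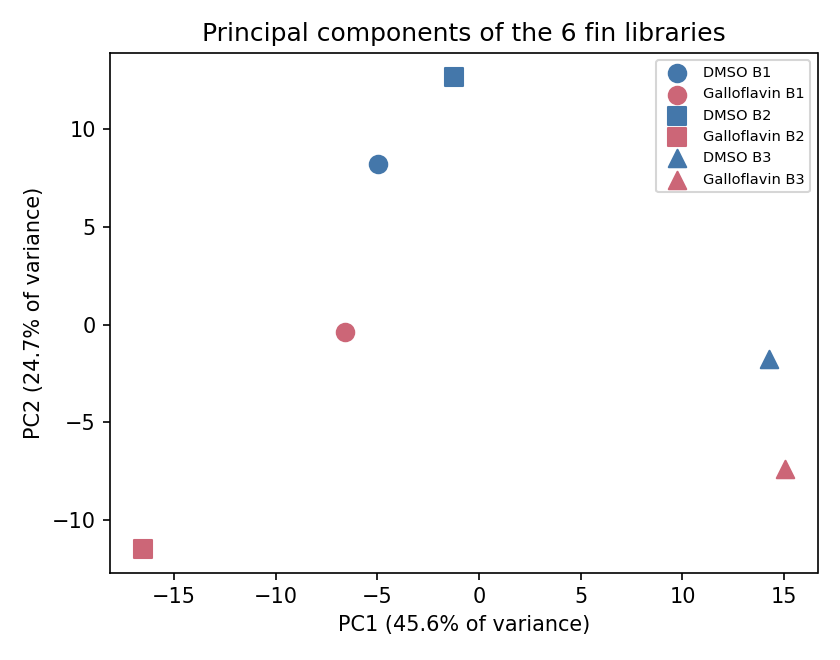
Scores of the 6 libraries on the first and second principal components (share of variance on each axis) of the 500 most variable genes, with colour for the group and marker shape for the batch. Both B3 libraries lie above 14 on the first component, and each Galloflavin library lies below its DMSO partner on the second.

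The comparison of Galloflavin with DMSO asked which genes differ in the early regenerate after the inhibitor is given. The data hold no measure of lactate or of enzyme activity. Cell cycle genes fell as a group, by a median of 0.22 on the log2 scale for 38 DNA replication genes and 0.23 for 46 mitosis genes (adjusted p = 0.623 for both with an estimated correlation). Genes of the circadian clock (median log2 fold change 0.22, 34 genes), inflammatory mediators (0.23, 47 genes) and neutrophil markers (0.27, 20 genes) rose as groups (adjusted p = 0.623 for each with an estimated correlation). In B3 the medians of the last 2 were -0.03 and -0.12. Glycolysis (0.55, 23 genes) and hypoxia response genes (0.42, 29 genes) also rose (adjusted p = 0.623 for both with an estimated correlation). Neither passed without Galloflavin B2 (means 0.11 and 0.08 against 0.45 and 0.50). Blastema and regeneration genes did not pass (median 0.02, 61 genes, camera adjusted p = 0.777), but passed as higher without DMSO B3 (mean 0.10 against 0.02). Of the 46 lists tested with camera, 10 rose and 5 fell, and 10 of these 15 had medians of the same sign in 3 batch pairs. None of the 15 passed with an estimated correlation (lowest adjusted p = 0.623) or with fry (lowest adjusted p = 0.545). The smallest exact permutation p that 3 libraries per group allow, 0.1, was reached by 3 of the 15 and by 5 of all 46 lists. By chance a share of 0.1 of the lists would reach it on average.

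No single gene passed limma at an adjusted p of 0.05 (lowest 0.253), with 1139 of 15806 genes at an unadjusted p under 0.05, 660 higher and 479 lower, where 790.3 would be the average by chance. Other groupings of the 6 libraries into 3 and 3 gave 109 to 2345 such genes, with 2345, 1285 and 1196 above the real count. Those above it kept both B3 libraries together. The 3 other groupings that part all batch pairs, as the real one does, gave 447, 274 and 336. With batch as a block the count of genes that passed was also 0, with 1582 genes at an unadjusted p under 0.05. On the recovered reads, edgeR called 0 genes (1140 at an unadjusted p under 0.05) and DESeq2 called 58 higher and 25 lower, or 123 higher and 23 lower with batch as a block. In simulated counts of this size DESeq2 made 36 false calls beside 36 true ones for genes changed 1.5-fold.

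The DNA replication list fell (camera adjusted p = 1.8e-14; adjusted p = 0.623 with an estimated correlation), with 37 of 38 genes below 0 and batch medians of -0.22, -0.29 and -0.15. Normalised counts of mcm2 (ENSDARG00000102798), a subunit of the replicative helicase, were 137 ± 6.80 (SD, n = 3) with DMSO and 94.9 ± 5.97 with Galloflavin, a log2 fold change of -0.53 ± 0.09 (SE; limma adjusted p = 0.381, DESeq2 adjusted p = 0.000297). The licensing factor cdc6 was at 10.24 ± 0.31 and 6.87 ± 0.0375 (-0.51 ± 0.11). These 2 genes passed when adjusted over the list alone (0.0192 and 0.0321), and 0 of the list passed over all genes. The log2 fold changes were -0.40 ± 0.11 for mcm5 and -0.52 ± 0.14 for slbp, which binds histone mRNA. The mitosis list fell as well (adjusted p = 2.1e-12; adjusted p = 0.623 with an estimated correlation), with all 46 genes below 0, batch medians of -0.33, -0.19 and -0.18, and 0 genes passing when adjusted over the list alone. Among its genes, anln stood at -0.41 ± 0.10, the proliferation marker mki67 at -0.33 ± 0.10, ccna2 at -0.32 ± 0.11 and the mitotic kinase plk1 at -0.35 ± 0.13. The mean of the mitosis list, -0.23, was -0.15 without Galloflavin B1 and -0.15 without DMSO B3, with its call kept in both. The groups overlapped, as the mean log2 value of the mitosis genes, centred over the 6 libraries, was 0.11 in Galloflavin B3. In DMSO B1 and DMSO B2 it was lower, at 0.049 and 0.009. The exact permutation p of the mitosis list was 0.3. Other groupings of the 6 libraries into 3 and 3 gave a lowest camera adjusted p down to 1.13e-22 over the lists. The groupings with a value below that of the DNA replication list (1.46e-17, 2.28e-19 and 1.13e-22) kept both B3 libraries together. The 3 other groupings that part all batch pairs, as the real one does, gave 5.1e-07, 7.71e-13 and 2.77e-11. A value as low as that of the mitosis list is therefore not particular to the grouping by Galloflavin. None of these 3 was as low as the DNA replication list, but 3 groupings are too few to decide this for that list. Other chromatin regulators fell by a median of 0.05 (adjusted p = 0.00842; adjusted p = 0.623 with an estimated correlation; 21 of 31 genes below 0), with dnmt3ab at -0.32 ± 0.09, uhrf1 at -0.40 ± 0.12, ezh2 at -0.38 ± 0.11 and suz12a at -0.32 ± 0.13. Of this list 0 genes passed when adjusted over the list alone, and its call ended without Galloflavin B3 (mean -0.04 against -0.08).

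The circadian clock list rose (adjusted p = 0.000401; adjusted p = 0.623 with an estimated correlation), with 24 of 34 genes above 0 and batch medians of 0.32, 0.02 and 0.21. The transcriptional repressor cry1a (ENSDARG00000045768) had 21.7 ± 1.65 normalised counts with DMSO and 45.2 ± 8.65 with Galloflavin (1.01 ± 0.15; limma adjusted p = 0.381, DESeq2 adjusted p = 1.34e-05). The repressor per2 (ENSDARG00000034503) had 28.4 ± 7.35 and 71.3 ± 18.2 (1.303 ± 0.24; limma adjusted p = 0.429, DESeq2 adjusted p = 0.000322). The nuclear receptor gene nr1d2a was at 1.23 ± 0.30 and nfil3 at 0.54 ± 0.14. These 4 genes passed when adjusted over the list alone (0.00663, 0.0141, 0.047 and 0.047), with 0 over all genes, and each was higher in the Galloflavin library of every batch.

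**Figure D2:**
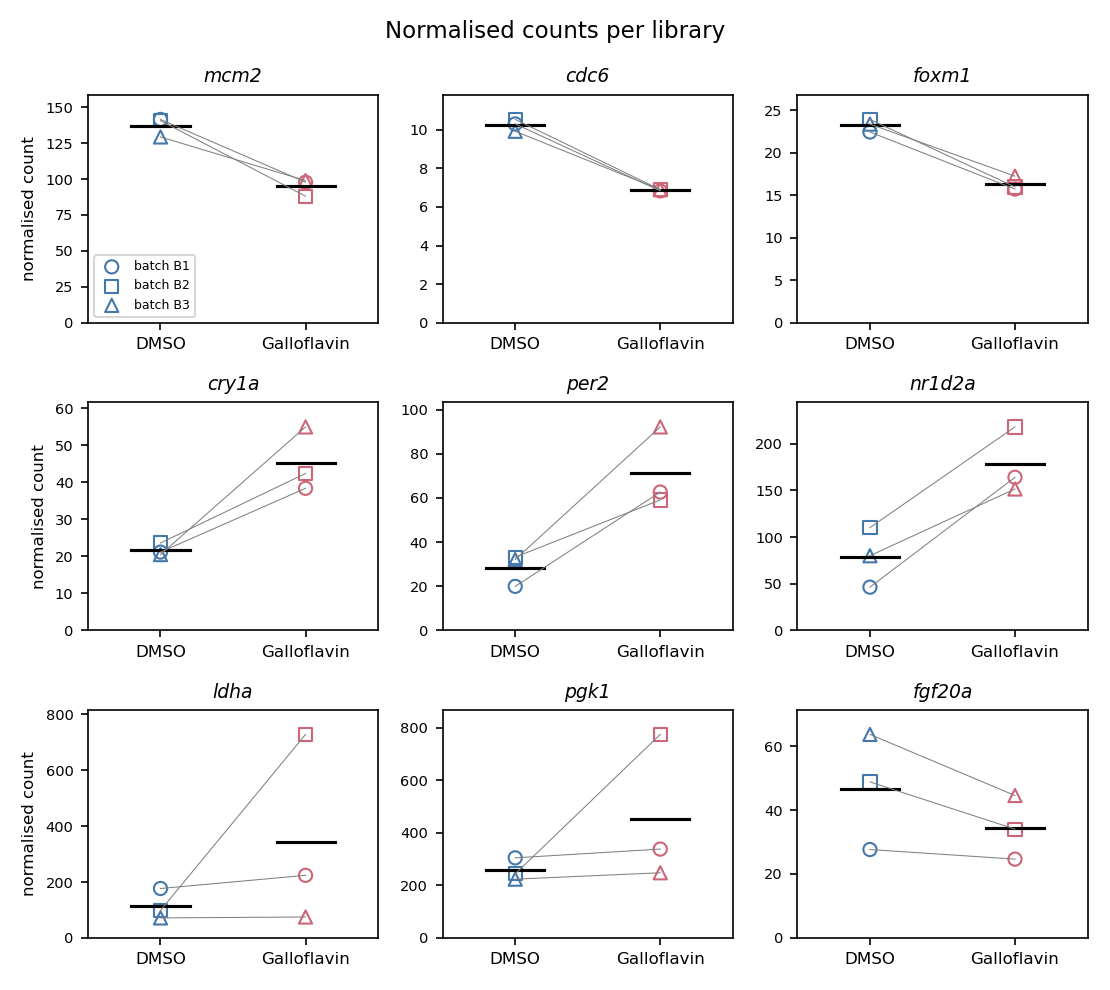
Normalised counts (vertical axis, linear from 0) of 9 genes in the 6 libraries, with markers and grey lines for the batches and a black bar for the group mean of 3 libraries. The genes mcm2, cdc6 and foxm1 are lower and cry1a, per2 and nr1d2a higher with Galloflavin in each batch, while ldha and pgk1 reach 728 and 775 in Galloflavin B2 alone.

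Inflammatory mediators rose (adjusted p = 0.000447; adjusted p = 0.623 with an estimated correlation), with 33 of 47 genes above 0 and 0 passing when adjusted over the list alone. The batch medians were 0.35, 0.26 and -0.03. The chemokine cxcl12a was at 0.71 ± 0.19, the complement gene c3a.1 at 1.65 ± 0.46, the metalloproteinase inhibitor timp2b at 0.66 ± 0.18 and nfkbiaa, an inhibitor of NF-kappaB, at 0.84 ± 0.24. These 4 passed DESeq2 with batch as a block and not without it. Neutrophil markers rose (adjusted p = 0.000592; adjusted p = 0.623 with an estimated correlation), with 18 of 20 genes above 0, batch medians of 0.63, 0.39 and -0.12, and 0 genes passing when adjusted over the list alone. Their call ended without batch B1 (mean 0.13 against 0.34), and with the call kept the mean was 0.22 without Galloflavin B1 and 0.52 without DMSO B3. The log2 fold changes were 0.93 ± 0.25 for lect2.1, 1.36 ± 0.48 for scpp8, and 0.59 ± 0.22 and 0.36 ± 0.13 for the NADPH oxidase subunits cybb and cyba.

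Macrophage markers did not pass (median 0.11, adjusted p = 0.0818) and rose with batch as a block (adjusted p = 0.0454; adjusted p = 0.788 with an estimated correlation). With the preset correlation they also passed without DMSO B1 (mean 0.20), DMSO B3 (0.21) or Galloflavin B2 (0.26), against 0.20 with all libraries, and with DESeq2 with the block but not with edgeR with it. In this list 2 of 28 genes passed when adjusted over the list alone, apoeb (0.72 ± 0.15), an apolipoprotein, and mfap4.1 (0.95 ± 0.21), while the complement genes c1qa (-0.79 ± 0.22) and c1qb (-0.56 ± 0.17) lay in the other direction. These genes were named after their values were seen. Interferon response genes (median -0.06), T and NK cell markers (-0.12) and osteoclast markers (0.10) did not pass (adjusted p = 0.659 to 0.768).

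Glycolysis genes rose (adjusted p = 0.000941; adjusted p = 0.623 with an estimated correlation), with 20 of 23 genes above 0, but the batch medians were 0.15, 1.39 and 0.06. The gene ldha (ENSDARG00000101251), which encodes the lactate dehydrogenase subunit that favours lactate production, had 177, 98.5 and 71.7 normalised counts in the DMSO libraries B1, B2 and B3 and 224, 728 and 74.9 in the Galloflavin libraries (1.09 ± 0.76, limma adjusted p = 0.793). Galloflavin B2 held the highest value of 17 of the 23 genes, and 15 lay at least 2-fold above the median of the other 5 libraries. The log2 fold changes were 0.34 ± 0.09 for eno3, 0.65 ± 0.38 for pgk1, 0.49 ± 0.31 for pklr and 0.77 ± 0.48 for pfkpa. Hypoxia response genes rose (adjusted p = 0.00248; adjusted p = 0.623 with an estimated correlation), with 25 of 29 genes above 0 and batch medians of 0.03, 1.18 and 0.03. The values were 1.05 ± 0.42 for bhlhe41, 0.92 ± 0.38 for bhlhe40, 0.65 ± 0.31 for hif1al and 0.59 ± 0.32 for the glucose transporter slc2a3a. In each list 0 genes passed when adjusted over the list alone. Without Galloflavin B2 neither list passed, and the means went from 0.45 to 0.11 for glycolysis and from 0.50 to 0.08 for hypoxia response, while without Galloflavin B3 they were 0.75 and 0.82.

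The lactate dehydrogenase gene ldhba was at 337 ± 31.6 normalised counts with DMSO and 373 ± 27.1 with Galloflavin (0.15 ± 0.10, adjusted p = 0.796). The lactate transporter gene slc16a3a was near 2 normalised counts in both groups (2.03 ± 0.85 and 1.87 ± 0.41). The transporter gene slc16a1a averaged 0.762 over the 6 libraries, below the filter, and ldhbb was not analysed here. Genes for pyruvate and lactate handling (median 0.02, 27 genes, adjusted p = 0.459), the TCA cycle (0.06, 22 genes, 0.226), the pentose phosphate pathway (-0.10, 9 genes, 0.507), serine and one-carbon metabolism (-0.21, 13 genes, 0.0749) and fatty acid oxidation (-0.002, 24 genes, 0.777) did not pass, with 0 genes each when adjusted over the list alone. The serine and one-carbon list passed as lower without DMSO B3 (mean -0.23) or Galloflavin B1 (-0.20), against -0.14 with all, and over all libraries with weights per library. Genes of lactylation and other acylations, most of which encode enzymes that write or remove these marks, also did not pass (0.02, 36 genes, adjusted p = 0.659, 0 when adjusted over the list alone). Nuclear-encoded oxidative phosphorylation genes rose by a median of 0.04 (adjusted p = 0.0415; adjusted p = 0.784 with an estimated correlation; adjusted p = 0.0549 with batch as a block), with 53 of 70 genes above 0. Of these, cox6b1 was at 0.48 ± 0.26, ndufb9 at 0.13 ± 0.08, ndufa5 at 0.18 ± 0.11 and ndufb4 at 0.15 ± 0.11. The mean of this list, 0.05, was 0.04 without DMSO B1, 0.04 without DMSO B2 and 0.01 without Galloflavin B2, each without a call. It kept its call in 7 of 15 alternatives over all libraries. It lost it with batch as a block, a minimum mean of 5, upper-quartile scaling, quantile normalization, and edgeR and DESeq2 with or without the block.

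Ribosomal protein genes rose by a median of 0.15 (adjusted p = 1.65e-12; adjusted p = 0.623 with an estimated correlation), with 75 of 77 genes above 0 and batch medians of 0.11, 0.28 and 0.08. The log2 fold changes were 0.24 ± 0.11 for rps18 and for rps14, 0.19 ± 0.09 for rpl31 and for rpl21, and quantile normalization ended the call (mean 0.02 against 0.15), while without DMSO B2 the list passed with a mean of 0.10. Myc and ribosome biogenesis genes fell by a median of 0.15 (adjusted p = 0.00287; adjusted p = 0.685 with an estimated correlation; 27 of 32 genes below 0), with batch medians of -0.13, -0.31 and 0.08. Values were -0.28 ± 0.14 for nop58, -0.32 ± 0.16 for nol6, -0.25 ± 0.13 for mybbp1a and -0.19 ± 0.11 for fbl. Cholesterol synthesis genes fell by a median of 0.18 (adjusted p = 0.00242; adjusted p = 0.623 with an estimated correlation; 19 of 22 genes below 0), with ebp at -0.58 ± 0.18, mvda at -0.38 ± 0.14, sqlea at -0.83 ± 0.30 and tm7sf2 at -0.38 ± 0.15. The genes ebp, sqlea and tm7sf2 lay below 4 normalised counts in all 6 libraries. A minimum mean of 5 ended the call of the list (mean -0.09). Genes of p53 and apoptosis rose by a median of 0.11 (adjusted p = 0.0216; adjusted p = 0.623 with an estimated correlation; 23 of 29 genes above 0), with casp9 at 0.49 ± 0.14, mcl1b at 0.51 ± 0.18, mcl1a at 0.31 ± 0.16 and sesn1 at 0.43 ± 0.23. In these 4 lists and the oxidative phosphorylation list 0 genes passed when adjusted over the list alone. Single libraries decided 3 of the calls. The mean of the Myc list was -0.08 without DMSO B1 and -0.01 without Galloflavin B2 (-0.11 with all), that of cholesterol synthesis -0.10 without either (-0.18), and that of the p53 list 0.05 without DMSO B1 and 0.11 without Galloflavin B3 (0.12), each without a call.

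Extracellular matrix and remodelling genes rose by a median of 0.08 (adjusted p = 0.0415; adjusted p = 0.685 with an estimated correlation; 34 of 49 genes above 0), with batch medians of 0.24, 0.16 and -0.08. The protease inhibitor gene serpine2 was at 0.46 ± 0.10 (DESeq2 adjusted p = 0.0339), the hyaluronan receptor gene cd44a at 0.43 ± 0.10, sdc4 at 0.39 ± 0.10 and timp2b at 0.66 ± 0.18. Basal epidermis markers rose by a median of 0.21 (adjusted p = 0.012; adjusted p = 0.623 with an estimated correlation; 15 of 21 genes above 0), with batch medians of 0.39, 0.17 and 0.17. The claudin genes cldni and cldn1 stood at 0.45 ± 0.13 and 0.46 ± 0.13, the cadherin gene cdh1 at 0.21 ± 0.08 and itga6b at 0.43 ± 0.19. The keratin gene krt5, also in this list and named after its values were seen, took 6.71%, 7.06% and 5.52% of reads in DMSO B1, B2 and B3. Its shares in Galloflavin B1, B2 and B3 were 5.18%, 6.22% and 5.51%. In both lists 0 genes passed when adjusted over the list alone. The matrix list lost its call without DMSO B1 (mean 0.08), Galloflavin B1 (0.05) or Galloflavin B2 (0.05, against 0.11 with all libraries) and with a pseudocount of 5, quantile normalization or edgeR, and its mean was 0.22 without Galloflavin B3. The epidermis list lost its call without DMSO B1 (0.12 against 0.16), with quantile normalization and with the symbols of the deposited table alone.

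Superficial and intermediate epidermis markers did not pass (median 0.06, adjusted p = 0.0806) but passed as higher without DMSO B1 or Galloflavin B1 (mean 0.08 in each, 0.05 with all), and with a minimum mean of 5, upper-quartile scaling or DESeq2. In this list 2 of 36 genes passed when adjusted over the list alone, the claudin gene cldne (0.59 ± 0.11) and the transglutaminase gene tgm1l1 (0.79 ± 0.18), named after their values were seen. Pigment cell markers did not pass (-0.15, adjusted p = 0.0752) and fell with batch as a block (adjusted p = 0.0261; adjusted p = 0.788 with an estimated correlation). They also passed as lower without DMSO B1 (mean -0.23) or Galloflavin B3 (-0.20), against -0.13 with all. So they did with a minimum mean of 5 and with edgeR and DESeq2 with the block. Markers of osteoblasts (median 0.02, mean and test below 0), fibroblasts and intraray mesenchyme (-0.01), endothelium (0.13), erythrocytes (-0.05), nerve and glia (0.06), and ionocytes and neuromasts (0.01) did not pass (adjusted p = 0.166 to 0.947), with 0 genes when adjusted over the list alone. Of these, fibroblast markers passed as lower without Galloflavin B2 (mean -0.10 against -0.01) and erythrocyte markers as higher without DMSO B1 (0.41 against -0.03). The lists for B cells (3 genes), skeletal muscle (4 genes) and mitochondrially encoded genes (0 genes) were too small to test.

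Of the regeneration genes that mark the wound epidermis and blastema, none passed in limma with or without batch as a block. Normalised counts of fgf20a, a growth factor gene required for blastema formation, were 46.7 ± 18.1 with DMSO and 34.4 ± 9.96 with Galloflavin (-0.39 ± 0.32, adjusted p = 0.823) and were lower in the Galloflavin library of each batch, by 0.16, 0.51 and 0.51 on the log2 scale. The homeobox gene msx1b was at 58.7 ± 11.4 and 54.6 ± 5.77 (-0.09 ± 0.15), wnt5b at 81.9 ± 13.3 and 73.9 ± 14.1 (-0.15 ± 0.17), and aldh1a2, which makes retinoic acid, at 61.4 ± 24.4 and 65.0 ± 10.4 (0.14 ± 0.26). The fibronectin gene fn1b was the most abundant of them at 12642 ± 1680 and 12899 ± 2050 (0.02 ± 0.18). The log2 fold changes were 0.09 ± 0.15 for junba, -0.03 ± 0.16 for il11a, -0.13 ± 0.18 for lepb, 0.61 ± 0.44 for the metalloproteinase gene mmp9 and -0.04 ± 0.76 for mmp13a. The aryl hydrocarbon response gene cyp1a was at -0.54 ± 0.55. All of these had adjusted p of 0.8 to 0.999 in limma. The signs for msx1b, aldh1a2, fn1b, junba, il11a, lepb, mmp9, mmp13a, cyp1a and slc16a3a changed with a left-out library or batch.

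The pathway lists did not pass, with medians of -0.11 for Wnt, -0.03 for Fgf, -0.12 for hedgehog and retinoic acid, 0.02 for BMP, TGF-beta and activin, -0.02 for Notch (mean 0.02) and -0.02 for insulin-like growth factor and mTOR (mean 0.13), at adjusted p = 0.0749 to 0.825. The Wnt list passed as lower without DMSO B1 (mean -0.10) or Galloflavin B2 (-0.14, against -0.09 with all). So did hedgehog and retinoic acid (-0.08 and -0.13 against -0.08), and Fgf without DMSO B1 (-0.17 against -0.04). Stress lists did not pass either, with medians of 0.12 for the integrated stress response, -0.002 for the unfolded protein response, 0.02 for heat shock, 0.05 for oxidative stress, 0.01 for the aryl hydrocarbon response and drug metabolism (mean -0.001) and -0.08 for immediate early genes (adjusted p = 0.0806 to 0.819). The integrated stress response passed as higher without DMSO B2 (mean 0.21) or Galloflavin B3 (0.25, against 0.16 with all). Immediate early genes passed as lower without DMSO B1 (-0.40 against -0.12). The unfolded protein response and heat shock lists passed as higher without Galloflavin B1 (0.19 and 0.39) and as lower without Galloflavin B2 (-0.14 and -0.22, against -0.01 and 0.07 with all). The small heat shock protein gene hspb1 (0.72 ± 0.14), named after its value was seen, passed when adjusted over its list alone, as the only gene of these 12 lists to do so.

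**Figure D3:**
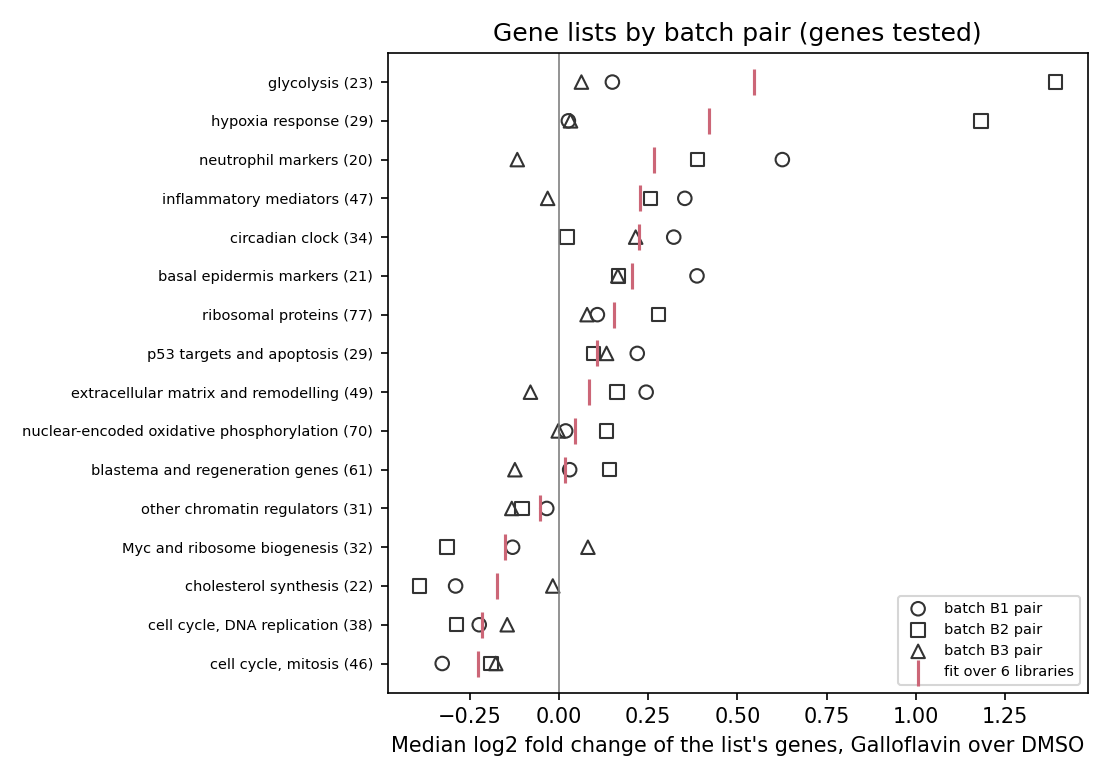
Median log2 fold change of Galloflavin over DMSO (horizontal axis) for the 15 gene lists that passed camera and for the blastema list, with the number of genes tested in brackets, open markers for the 3 batch pairs and a red bar for the fit over all 6 libraries. Both cell cycle lists lie below 0 in every batch, and the medians of the glycolysis and hypoxia response lists are 1.39 and 1.18 in B2 but at most 0.15 in the others.

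The genes with the lowest unadjusted p did not pass limma (adjusted p = 0.253 to 0.572). The rule that named them required the same sign in 3 batches. All 20 passed DESeq2, which used the same libraries and so is no independent support, and with batch as a block the 10 higher genes and 5 of the lower passed it. Those higher with Galloflavin were the acyltransferase gene mboat1 (24.6 ± 1.27 against 42.7 ± 0.72, 0.77 ± 0.09), cry1a, lpar6b (0.77 ± 0.11), cmip (0.54 ± 0.08), rhoub (0.84 ± 0.13), ppdpfb (0.65 ± 0.10), rasgrp4 (0.97 ± 0.15), pik3ip1, an inhibitor of PI3 kinase signalling (0.81 ± 0.13), the arrestin-domain gene arrdc2 (85.4 ± 11.3 against 257 ± 97.8, 1.52 ± 0.26) and tmprss13b (1.13 ± 0.19). Those lower were jac4 (41.7 ± 4.05 against 17.8 ± 3.16, -1.20 ± 0.15), cdca7a (-0.66 ± 0.10), mcm2, nlrc5 (-0.74 ± 0.13), foxm1, a transcription factor of mitotic genes (23.3 ± 0.75 against 16.3 ± 0.81, -0.49 ± 0.10), znf367 (-0.69 ± 0.14), hcfc1a (-0.44 ± 0.09), alpi.1 (-0.67 ± 0.13), cdc6 and glceb (-0.46 ± 0.09).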

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

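Upper-quartile scaling, the set tests with an estimated correlation or fry together with the replicate block, the lists with the deposited symbols alone, the other thresholds for lists and the left-out libraries per list were chosen after the results were seen. The count of 0 genes in limma held under the other scalings, filters, pseudocounts, thresholds, library weights, robust moderation, the replicate block (0 genes) and edgeR with and without it, and moved to 83 with DESeq2 and to 146 with DESeq2 and the replicate block (the cause was not tested). With a library or a batch left out it ran from 0 to 1, the 1 being mhc2dab without batch B2. The 15 list calls became 0 with an estimated correlation, 0 with it and the replicate block, 0 with fry and 0 with fry and the replicate block, where the preset correlation is replaced by one that widens the test or each list is tested by itself. At adjusted p thresholds of 0.1 and 0.01 they were 21 and 11. They were 11 to 16 at 0.05 in the other alternatives over all libraries, 11 with quantile normalization and 16 with the paired fit, of which 14 were shared, and 15 to 20 with a library or batch left out, of which 9 to 15 were shared. Except for the oxidative phosphorylation, macrophage and pigment lists, the replicate block changed no other list call in limma. The lists for DNA replication, mitosis, inflammatory mediators and the clock kept their calls in all 15 alternatives over 6 libraries with the preset correlation and all 9 left-out settings. Apart from the oxidative phosphorylation list without batch B2, no result that had passed a test turned in sign, and the signs of the following turned (the cause was not tested). The change of mmp13a was 0.12 with a pseudocount of 0.5, 0.00777 with quantile normalization, 0.61 with library weights, 0.25 with edgeR and 0.81 with DESeq2, both with the replicate block. That of fn1b was -0.0104 with upper-quartile scaling, -0.0479 with quantile normalization and -0.00419 with library weights, that of junba -0.0572 with quantile normalization and that of il11a 0.0242 with library weights. The mean of the blastema list was -0.0179 with upper-quartile scaling, -0.0329 with quantile normalization, -0.0175 with edgeR and -0.0163 with DESeq2, and that of the superficial epidermis list -0.00445 with quantile normalization. With a library or batch left out, values ran from -0.0764 to 0.13 for the blastema list, -0.00224 to 0.0847 for oxidative phosphorylation, -0.37 to 0.26 for slc16a3a, -0.0849 to 0.16 for fn1b, -0.16 to 0.0884 for il11a, -0.0690 to 0.44 for aldh1a2, -0.61 to 0.95 for mmp13a, -0.0753 to 0.19 for junba, -0.19 to 0.0603 for msx1b, -0.29 to 0.0233 for lepb, -0.94 to 0.13 for cyp1a and -0.00254 to 1.08 for mmp9. No scaling moved the median of all genes by 0.1. With 17712157 reads or more, depth limits genes near the filter, such as slc16a3a.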

Other observations

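Apart from the tests of muscle, glucocorticoid and fasting genes, the tests given here were chosen after the results were seen. For glucocorticoid and fasting genes the bar set beforehand was a high percentile among matched lists, which both lists met, and the need to pass with an estimated correlation was added after the percentiles were seen. The glucocorticoid and fasting lists were picked because arrdc2, pik3ip1 and clock genes led the table of genes. Among gene families grouped by the stem of their symbol, 13 of 235 families with at least 8 genes passed camera with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.996), 8 rising and 5 falling. Those that fell were the mcm (10 of 10 genes below 0, median -0.34), phf (16 of 19, -0.10), dhx (13 of 15, -0.17), kif (27 of 31, -0.12) and timm genes (13 of 14, -0.10), with a kif median of 0.01 in B1. The rising families not described below were rpl (40 of 43 above 0, median 0.15), rps (41 of 44, 0.15), cxcl (7 of 8, 0.29) and tspan (17 of 21, 0.11). Of the members, 7 of 10 mcm, 41 of 43 rpl, 33 of 44 rps and 5 of 8 cxcl genes are in the fixed lists, so these families largely repeat them. Members of the ESCRT-III complex, which cuts membrane necks in endosomes and at abscission, rose together (chmp genes, 11 of 11 above 0, median 0.17, adjusted p = 0.000766), with batch medians of 0.13, 0.12 and 0.23. Their values were 0.29 ± 0.08 (SE, 3 libraries per group) for chmp1b, 0.24 ± 0.08 for chmp5b and 0.24 ± 0.09 for chmp1a. Claudin genes, which seal epithelial junctions, rose (12 of 13, median 0.17, adjusted p = 0.0158), with cldn23.1 at 0.57 ± 0.16 and cldn7b at 0.47 ± 0.13. Krüppel-like factor genes rose (13 of 17, median 0.28, adjusted p = 0.0256), with klf3 at 0.62 ± 0.16 and klf9 at 0.83 ± 0.29, and mfap genes rose (8 of 9, median 0.27, adjusted p = 0.0256), with the low-count paralog mfap4.2 at 1.94 ± 0.44. The medians of all 13 families kept their sign under median-of-ratios, upper-quartile and quantile scaling and without Galloflavin B2. The class II gene mhc2dab was at 0 normalised counts in DMSO B1 and DMSO B3, 14.8 in DMSO B2 and 25.7, 9.56 and 26.1 in the Galloflavin libraries B1, B2 and B3. These families and genes, and the glucocorticoid, fasting and hypoxia targets given with values below, were named after their values were seen.

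With 3 libraries per group the 10 splits of the libraries cannot give a share under 0.05. The real split gave 0 genes in limma and 15 lists, and the highest other split gave 3 genes and 20 lists (10 of 10 and 5 of 10 splits gave at least the real count). For DESeq2 the real split gave 83 genes and the highest other 363, and 3 of 10 splits gave at least 83. The 363 genes came from both B1 libraries and DMSO B2 against the rest, which points to a structure of the samples. The splits that kept both B3 libraries together gave 363, 151 (DMSO B1 with both B2 libraries), 24 (both B1 libraries with Galloflavin B2) and 19 genes. Those that parted the B3 libraries gave 0 to 4, apart from the 83 of the real split. The layout of B3 may therefore play a part, which these counts do not settle. Among the 3 other splits that part all batch pairs, as the real split does, DESeq2 called at most 4 genes, limma 0 and camera 19 lists.

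Lower cell cycle transcripts in the Galloflavin libraries were weighed first. Scaling and the library Galloflavin B2 alone are argued against, since the cell cycle median was -0.2488 or lower with quantile and upper-quartile scaling and -0.197 without Galloflavin B2, against -0.23 with all libraries. If cells that do not divide had diluted the fin cells, the 79 markers of fibroblasts, osteoblasts and endothelium would lie as low as the 84 cell cycle genes, and 2 earlier versions of the test argued against this, with a difference of 0.2429 over genes (bootstrap SE 0.0306) and a mean of 0.2623 over the 3 pairs (SE 0.103). The bootstrap SE treats genes that vary together as independent and does not measure variation between pools. The version kept, set after these values were known, asks for 2 SE in each pair and fails in B3 (0.0674, markers at -0.10 and cell cycle genes at -0.17), so by that rule alone dilution cannot be told apart from a change within the fin cells. Another hypothesis that stays open is that Galloflavin may slow proliferation in the early regenerate, which the estimated-correlation p of 0.623 and the count of splits leave undecided.

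The glycolysis genes of Galloflavin B2 form the second pattern. Muscle in the pool is argued against, as summed muscle markers rose by 0.106% of the rise of summed glycolysis genes. An effect common to Galloflavin pools is argued against for the hypoxia list (median difference at most 0.03186 in the other pairs, 1.18 in B2) but stays open for glycolysis, at 0.1493 in B1, 0.06 in B3 and 1.39 in B2, with eno3 higher in all 3 pairs (0.47, 0.41 and 0.14). The bar was a fixed small share of the B2 difference, set after the results were seen. Glycolysis exceeded it narrowly, in B1 alone, so the unlike readings of these lists rest on that cut-off. Outside glycolysis, 11 of 15 hypoxia targets were highest in Galloflavin B2, but these genes belong to the list whose rise had been seen, so the count does not test a low oxygen state of that pool, which stays open in the fish or in handling. Both B1 libraries were above DMSO B2 and the B3 libraries in some of these targets, with egln3 at 24.3 and 22.0 normalised counts in DMSO B1 and Galloflavin B1, 109 in Galloflavin B2 and 3.79 to 4.45 elsewhere, and ankrd37 at 14.4 and 16.3, 70.9, and 2.39 to 2.71.

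The clock genes form the third pattern. A shift of clock phase, including another hour of collection, would lower genes of the bmal and clock arm in each batch. Their mean pair differences were 0.1171 in B1 (SE 0.117), -0.40 in B2 and -0.16 in B3. In the opposite per and nr1d arm 12 of 16 genes lay above 0 (median 0.28). The others were per1b (-0.0008), dbpa (-0.01), dbpb (-0.05) and tefa (-0.07), named after their values were seen. With 6 genes in the bmal and clock arm, phase cannot be told apart from an input to per2 and cry1a. Glucocorticoid targets outside the fixed lists had a median of 0.44 (12 of 14 genes above 0; pair medians 0.67, 0.20 and 0.11), at percentile 100 of 10000 lists matched on expression, with fkbp5 at 1.03 ± 0.24 and mt2 at 0.84 ± 0.23. Targets of FoxO and fasting had a median of 0.33 (13 of 19 genes above 0, 4 of the 19 in the fixed lists; pair medians 0.33, 0.16 and 0.22) and 0.19 without Galloflavin B2, at percentiles 100 and 99.99, with txnipa at 0.77 ± 0.20 but ulk1a at -0.46 ± 0.12. The percentiles take no account of correlation between genes, and with an estimated correlation neither list passed (camera adjusted p = 0.0629 and 0.0814 over these 2 lists; 0.000217 and 0.00162 with the preset one), so a stress hormone or fasting state may or may not have reached the fin.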
